A study of Mus musculus with 2 samples.

How the data were processed

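The series held ATAC-seq of megakaryocyte progenitor primary cells from male C57BL/6J mice aged 5 to 6 weeks, with 2 libraries of 50000 cells that the labels number as biological replicates of 1 group. The labels also carry the code CFU-M, which was not interpreted. The label of replicate 1 names a HiSeq 2000 and a NextSeq 500, and no instrument was used to split the data.

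The files analysed were peak lists on mm10, per the labels. Each list gives, per the deposited file descriptions, a narrowPeak record for each summit. The signal of a peak is the value the authors' peak caller gave it, with no scaling between libraries stated. The p and q columns are -log10 values that the authors deposited, the smallest -log10 p being 2.00 to 2.01 in each list. Lists were made by the authors from each library alone (thresholded on the irreproducible discovery rate, IDR, or by pseudoreplicates) and from both libraries together (conservative IDR-thresholded and IDR-thresholded lists, replicated and pseudoreplicated lists). A ranked list of matched summit pairs gives for each pair the authors' score, the -log10 of its global IDR, and the -log10 p of each input. It does not name its inputs. Their intervals and -log10 p values recur in both libraries' own lists, so they were taken to be the peaks of both libraries. They were not assigned to replicates. The aligner, the peak caller, their versions, the handling of duplicates and mitochondrial reads and any shift of reads for the transposase are not given in the sources used here. These steps could change how many regions are listed and where their summits lie. Signal tracks and alignments were not used here, and depth per library is unknown.

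Summits sharing an interval were merged into regions, and a region's signal is that of its strongest summit. Coordinates are 1-based. The reference was GRCm38.p6, the assembly of mm10, with GENCODE M21 annotation (21938 protein-coding genes with 54361 start sites). The lists covered 21 chromosomes, and no peak ran past the end of a reference chromosome. A region was shared between replicates when at least 50% of either region was covered. Shuffles placed regions at random within their chromosome 100 times. Location was taken from the strongest summit, in the order promoter (within 1 kb of a protein-coding start site), exon, intron, intergenic.

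The 17 gene lists and 21 motif consensus sequences, the tests, their settings and the rule for named genes were fixed before the data were examined. Of 359 list genes 1, Ahsp, had no match in the annotation and was left out, and Mkl1 was matched to its current symbol Mrtfa. Promoter peaks in lists were tested by Fisher's exact test against all other protein-coding genes, with 0.5 added to each count for the odds ratio. Distal regions within 50 kb were tested by permutation, two-sided, with 100000 random lists matched in 5 bins on the number of start sites within 50 kb. Motifs were matched on both strands in windows of 75 bp each side of the summit and in windows centred 1 kb up- and downstream that overlap no peak of the most inclusive list. Benjamini-Hochberg adjustment ran over the 17 lists, over the 7 lineages, and over the 42 motif tests. The threshold was an adjusted p of 0.05. Genes, regions and windows are not replicates, so these p-values describe this set of peaks.

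The rule named, from each list, the 3 members with the highest promoter signal in the conservative list that also had a promoter peak in both replicates, and up to 3 members in list order without a promoter peak. From the 2 megakaryocyte lists together it named the 6 with the highest promoter signal and the 4 with most distal regions. From all genes it named the 8 with most distal regions, the gene nearest each of the 5 strongest regions outside promoters, and the gene nearest each of the 3 strongest regions found in no list of the other replicate. The reading of this rule was corrected to its wording after results had been seen. Some genes that the rule named are not reported here.

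Alternatives were other overlap rules, other peak lists, the stronger 50% of regions by signal, each replicate's own list alone, promoter windows of 0.5 and 2 kb, locus windows of 20 and 100 kb, matching on promoter CpG density, no matching on gene density, motif windows of 50 and 100 bp each side, flanks of matched GC content and dinucleotide shuffles. For the GC match, as many summits as flanks were drawn at random in each bin of GC content, so summits without a matching flank were left out. The gene density used for matching was first counted as gene 5′ ends and then corrected to annotated start sites, after results had been seen. The earlier count was kept as an alternative.

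The procedures were tested on simulated data with known answers. Of 1000 unchanged simulated lists 3.90% had a Fisher p under the threshold, and of 300 unchanged gene-dense lists 4.67% had a permutation p under it. In the latter, counts were drawn independently for each gene and depended only on the bins used for matching. Neighbouring genes that share distal regions were not simulated. Each of 100 simulated lists with 23 of 24 genes positive was called. Of 20000 simulated windows, 9.87% were found to hold a CTCF site where 9.88% had been given one. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and BLAST 2.17.0 were used. Regions were compared with the mitochondrial genome by BLAST (at least 50 bp at 90% identity). They were also compared with the reference, including the mitochondrial genome, for second copies (95% identity over 80% of the region).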

Results

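Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in megakaryocyte progenitors. These are blood precursors that give rise to megakaryocytes, the cells that release platelets. The primary cells came from male C57BL/6J mice aged 5 to 6 weeks, and each library was made from 50000 cells. There was 1 group with 2 biological replicates and no other condition. The comparisons were therefore between the replicates, between parts of the genome, between gene lists and between sequence motifs. The peak list of replicate 1 held 61735 open regions covering 32.8 Mb, and that of replicate 2 held 60098 regions covering 30.4 Mb. The conservative list made from both libraries, on which the location, gene and motif results rest, held 80938 regions covering 43.0 Mb with a median width of 454 bp. Read counts were not used here, so the depth of each library is unknown. Signal values are the authors' own per peak, and no scaling between the libraries is stated. Values given as mean ± SD are over the replicates' own lists, and intervals cover counting error only.

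The first comparison asked how far the open regions of both replicates coincided. Of the regions of replicate 1, 84.6% (52201 of 61735; Wilson 95% interval 84.3 to 84.8) were shared with replicate 2, and 87.4% (52524 of 60098; 87.1 to 87.7) of those of replicate 2 were shared with replicate 1. Regions of replicate 1 moved to random positions on their chromosomes were shared in 1.61% on average and in at most 1.78% over 100 shuffles. The strongest 10% by signal was shared in 99.7% of regions of replicate 1 and 99.9% of replicate 2, and the weakest 10% in 63.7% and 70.3%. In both replicates 99.3% of the regions overlapped the longer pseudoreplicated list of the other. Only 401 regions of replicate 1 and 388 of replicate 2 overlapped no region in any list of the other replicate. The strongest region of this kind in replicate 1 lay in an intron of Adgra1, which encodes an adhesion G protein-coupled receptor (chromosome 7, 139861499 to 139861767, signal 10.01). Next came a region in an intron of Ablim3, nearest to the 5′ end of Afap1l1 (signal 9.46). Another lay 60.6 kb from the 5′ end of Snap25 (chromosome 2, 136652368 to 136652915, signal 9.22). In replicate 2 the strongest such region lay in an intron of Epm2a, the gene of the glycogen phosphatase laforin (chromosome 10, 11362359 to 11362614, signal 13.5). The others were intergenic. Lcorl was nearest to one, though 1037 kb away (chromosome 5, 46894073 to 46894399, signal 11.01), and Stk38 to the other, 7.84 kb away (chromosome 17, 29015590 to 29015956, signal 10.4). One library per side allowed no test of a single region.

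**Figure D1:**
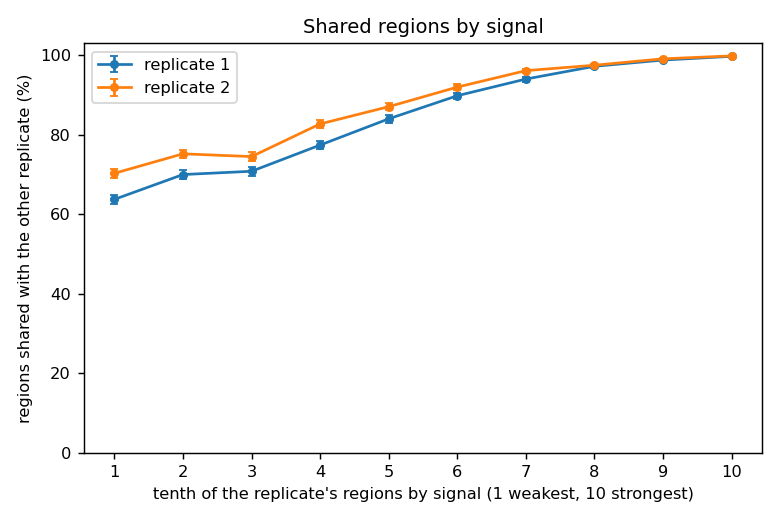
Share of each replicate's regions that the other replicate shared (vertical axis, %) by signal ranking in steps of 10% (horizontal axis, 1 weakest, 10 strongest), with Wilson 95% intervals. Replicate 1 ran from 63.7% to 99.7% and replicate 2 from 70.3% to 99.9%.

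Signal was compared in the regions that both replicates listed. Across these 51928 matched regions the Spearman correlation of signal was 0.916 and Pearson's r of log2 signal was 0.926. The authors' ranked list of 187397 summit pairs does not name its inputs, which were taken from their values to be the lists of both libraries. Over all its pairs the Spearman correlation of -log10 p was 0.822. Over the 118986 pairs within an IDR of 0.05 it was 0.804. The median log2 ratio of replicate 2 to replicate 1 was 0.08, and after removal of this median the ratios had an SD of 0.18. The ratio was 0.09 at the median in 12667 promoter regions and 0.08 in 39261 other regions. Regions are not independent replicates, so no p-value was computed.

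Open regions were concentrated at promoters of protein-coding genes. Promoters, taken as sequence within 1 kb of an annotated start site, held 19.01% of the regions (15389; Wilson 95% interval 18.7 to 19.3), against 2.61% of the same regions at shuffled positions, a ratio of 7.27. Introns held 39.5% of the regions (37.0% when shuffled) and exons 3.17% (2.50%). Intergenic sequence held 38.4%, below the shuffled 57.9%. The promoter share was 22.3% in replicate 1 and 22.7% in replicate 2, a mean of 22.5% ± 0.236 (SD, n = 2), both above the conservative list, which holds more regions. Promoter regions were also wider, with a median of 773 bp against 419 bp in introns and in intergenic sequence. None of the 100 shuffles gave a promoter share above 2.74%.

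**Figure D2:**
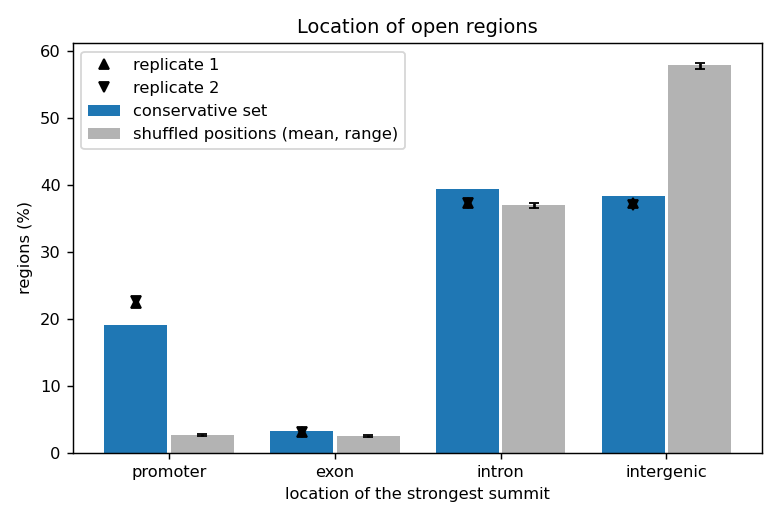
Share of regions (vertical axis, %) by location of the strongest summit for the conservative list (blue bars) and for shuffled positions (grey bars, mean with the range of 100 shuffles), with each replicate as a triangle. The promoter share was 19.01% against 2.61% when shuffled.

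The megakaryocyte gene lists were set against all protein-coding genes, of which 61.0% (13386 of 21938) had a promoter peak. All 24 megakaryocyte regulators, transcription factors such as Gata1, Fli1 and Runx1, had one (Wilson 95% interval 86.2 to 100), as did 91.7% of them in each replicate. Among 30 megakaryocyte and platelet genes 21 had one, 70% (52.1 to 83.3), with 50% in replicate 1 and 56.7% in replicate 2. The highest promoter signals were at Mrtfa, a coactivator of serum response factor (chromosome 15, 81012281 to 81190757, mean signal 15.98 ± 0.541, SD, n = 2), Cd226, an adhesion receptor (13.6 ± 1.51), and Gp1ba, a subunit of the platelet receptor for von Willebrand factor (chromosome 11, 70639122 to 70642036, 12.6 ± 0.114). The thromboxane synthase gene Tbxas1 (11.7 ± 1.00) and Ets1 (11.99 ± 1.10) were also among the 6 highest of both lists. In the conservative list their promoter signals ranked only 5100 and 5693 among all genes with a promoter peak. In the conservative list no promoter peak was listed at Ppbp, which encodes a platelet chemokine, at Gp1bb, or at Gp6, a collagen receptor gene of platelets. By Fisher's exact test, two-sided and adjusted by Benjamini-Hochberg over 17 lists, the regulators exceeded the other genes (log2 odds ratio 4.97 with 0.5 added to each count, adjusted p = 7.06e-05) and the platelet list did not pass the test (0.53, adjusted p = 0.401). With only the 50% of regions strongest in signal, the regulators' log2 odds ratio was -0.63 (exact test, adjusted p = 0.376). The median promoter signal was 7.38 in this list and 7.67 in the platelet list, against 11.2 over all genes with a promoter peak. Against random lists matched on promoter CpG density, which averaged 50.3%, the platelet list passed the threshold (permutation test, adjusted p = 0.0452), as it did in the pseudoreplicated list of both libraries (exact test, adjusted p = 0.0163).

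Lists of other cell types and processes fell on both sides of the other genes. Of the 17 lists, 5 had promoter peaks more often than other genes, 5 less often, and 7 did not pass the test. Besides the megakaryocyte regulators, promoters were open at all 25 cell cycle genes (exact test, adjusted p = 7.06e-05), all 20 housekeeping genes (adjusted p = 0.000281), 23 of 24 cytokine receptor and JAK-STAT genes (adjusted p = 0.000527) and 22 of 24 erythroid genes (adjusted p = 0.00311). Random lists matched to them on CpG density averaged 84.4%, 79.9%, 74.9% and 46.8%. Against these, each list still passed (permutation tests, adjusted p = 0.0480, 0.0319, 0.0144 and 0.00034 in the same order). Espl1, the gene of the protease separase (19.5 ± 0.981, SD, n = 2), Bub1 (16.9 ± 1.02) and Birc5 (14.9 ± 1.39) had the highest signals among the cell cycle genes, Hprt, Psmb2 and Sdha among the housekeeping genes, and Il6st (14.5 ± 0.377) and Jak1 (13.5 ± 2.06) were among the highest in the cytokine list. Trim10 (15.5 ± 1.14), Sptb and Epb41 led the erythroid list, in which Alas2, the erythroid enzyme of heme synthesis, and Slc4a1 had no promoter peak. Promoter peaks were less frequent at liver genes (3 of 20, adjusted p = 0.000135), germ cell genes (3 of 20, adjusted p = 0.000135), muscle genes (5 of 20, adjusted p = 0.00399), mast cell, basophil and eosinophil genes (5 of 18, adjusted p = 0.0116), and T and NK cell genes (8 of 22, adjusted p = 0.0450), all by the same exact test. The conservative list held no peak at the promoters of Alb, Apoa1 and Ttr in the liver list, Prm1, Prm2 and Tnp1 in the germ cell list, Myod1, Myog and Acta1 in the muscle list, Cpa3, Fcer1a and Ms4a2 in the mast cell list, or Cd3e, Cd3g and Cd4 in the T and NK cell list. Cpa3 had a promoter peak in the list of replicate 2 (signal 6.44). Open promoters in those lists included the germ cell genes Dazl (17.4 ± 0.241, SD, n = 2), Stra8 (16.7 ± 1.06) and Zpbp, Apob (16.6 ± 2.60) and Apoh in the liver list, Actn2 (15.2 ± 0.797), Ryr1 and Tnni2 in the muscle list, Cd3d (14.95 ± 0.377), Il7r and Lat in the T and NK cell list, and Il1rl1 (10.99 ± 0.759), Hdc and Il4 in the mast cell list.

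Among the lists that did not pass, stem and multipotent genes had promoter peaks at 16 of 20 (exact test, adjusted p = 0.152), led by Mllt3, Flt3 and Mecom and without a peak in the conservative list at Ly6a, Procr and Slamf1, the last of which had one in replicate 2 (signal 7.19). Granulocyte genes had them at 15 of 20, led by Camp, S100a8 and S100a9 and without one at Prtn3, Mmp9 and Lcn2, and monocyte and macrophage genes at 15 of 20, led by Adgre1, Irf8 and Siglech and without one at Csf1r, Marco and C1qa (exact test, adjusted p = 0.309 for both). B cell genes had them at 8 of 20 (exact test, adjusted p = 0.102), with high signals at Cr2 (18.6 ± 0.386, SD, n = 2), Bank1 (17.0 ± 0.465) and Pax5 (15.9 ± 0.315) and no peak at Cd79a and Vpreb1. Endothelial genes had them at 11 of 17 and neuronal genes at 13 of 20 (exact test, adjusted p = 0.821 for both). Cdh5, Plvap and Sox18 led the endothelial list, in which Tie1, Emcn and Robo4 had none in the conservative list and Robo4 had one in replicate 2 (signal 9.29). Snap25 (22.1 ± 0.0134), Syn1 and Map2 led the neuronal list, in which Syt1, Gad1 and Neurod1 had none. Against lists matched on CpG density, granulocyte (permutation test, adjusted p = 0.00586) and monocyte genes (adjusted p = 0.0144) passed the threshold on the higher side. By the same permutation test the liver (adjusted p = 0.0588), T and NK cell (adjusted p = 0.831) and mast cell lists no longer passed. The mast cell list was 0.657 percentage points above its matched lists. The muscle (adjusted p = 0.0196) and germ cell lists (adjusted p = 0.00113) still passed on the lower side (permutation tests). With only the 50% of regions strongest in signal, the housekeeping list (-0.23, exact test, adjusted p = 0.823), the erythroid (exact test, adjusted p = 0.284), cytokine (adjusted p = 0.467) and T and NK cell lists (adjusted p = 0.189) no longer passed. In the longer replicated list, the mast cell (adjusted p = 0.498) and T and NK cell lists (adjusted p = 1) no longer passed, while the stem (adjusted p = 0.0240) and endothelial lists (adjusted p = 0.00642) did, all by exact tests. The same 4 calls changed in the pseudoreplicated list (exact tests, adjusted p = 0.675, 1, 0.0138 and 0.00567). With promoter windows of 2 kb the mast cell (adjusted p = 0.141) and T and NK cell lists (adjusted p = 0.0723) did not pass and the granulocyte list did on the higher side (exact tests, adjusted p = 0.0330). The B cell list passed on the lower side with windows of 0.5 kb (adjusted p = 0.0187) and without replicate 1 (exact tests, adjusted p = 0.00829).

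**Figure D3:**
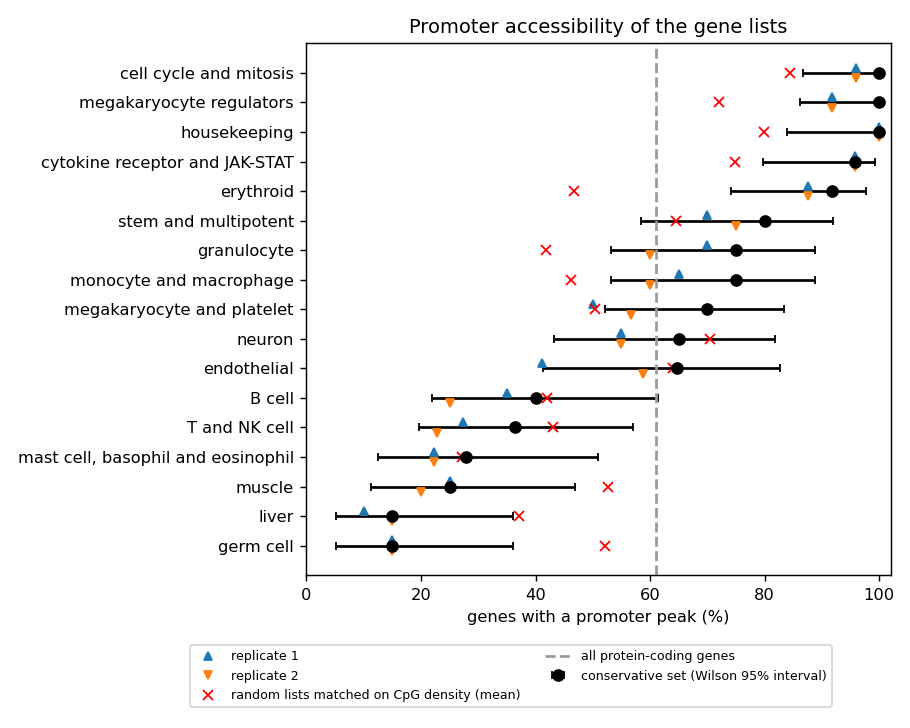
Share of each list's genes with a promoter peak (horizontal axis, %) in the conservative list (black, Wilson 95% interval) and in each replicate (triangles), with the mean of random lists matched on CpG density (crosses) and the share of all protein-coding genes (dashed line). All 24 megakaryocyte regulators had a peak, against 61.0% of all genes.

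Distal open regions were counted within 50 kb of each gene's 5′ end, leaving out promoters. Megakaryocyte regulators had 9.46 distal regions per gene on average and megakaryocyte and platelet genes 6.93, against 4.20 over all protein-coding genes. The regulators had 7.04 in replicate 1 and 6.54 in replicate 2, and the platelet genes 5.07 and 4.87. Fli1, an ETS transcription factor required for megakaryocyte development, had 21 distal regions in the conservative list, the second-highest count of all genes there (chromosome 9, 32422204 to 32542861). In the replicates' own lists Fli1 had 14 ± 1.41 (SD, n = 2), below Zfp217 with 16.5 ± 0.707. Zfpm1, the GATA cofactor FOG-1, had 17 (11 ± 0, SD, n = 2, in the replicates), the tetraspanin gene Cd9 16 (7.5 ± 0.707) and Bach1 15 (13.5 ± 0.707). The promoter signals of Fli1, Zfpm1, Cd9 and Bach1 were 5.53, 6.01, 4.96 and 6.45, against the median of 11.2 over all genes with a promoter peak. Fli1 had no promoter peak in the list of replicate 1, and Cd9 had none in either replicate's list. Against 100000 random lists matched on the number of start sites within 50 kb, the mean of log2(1 + regions) was higher by 1.29 for the regulators and by 0.80 for the platelet list (permutation test, two-sided, adjusted p = 0.000113 for both; raw p of 2.0e-05, the smallest the permutations can give).

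Of the 17 lists, 10 had more distal regions than matched random lists, none had fewer, and 7 did not pass the test. Besides both megakaryocyte lists these were granulocyte genes (log2 difference 1.02, adjusted p = 0.000113), monocyte and macrophage genes (0.96, adjusted p = 0.000204), cytokine receptor genes (0.83, adjusted p = 0.000204), erythroid genes (0.73, adjusted p = 0.00210), housekeeping genes (0.71, adjusted p = 0.00253), endothelial genes (0.59, adjusted p = 0.0403), cell cycle genes (0.58, adjusted p = 0.0115) and stem and multipotent genes (0.54, adjusted p = 0.0488), all by the permutation test. The lists of mast cell (0.43, adjusted p = 0.134), germ cell (0.27, adjusted p = 0.367), T and NK cell (0.25, adjusted p = 0.367), liver (0.20, adjusted p = 0.515), B cell (0.11, adjusted p = 0.698), muscle (0.03, adjusted p = 0.907) and neuronal genes (-0.47, adjusted p = 0.120) did not pass the permutation test. Over all genes the highest count in the conservative list was 22 at Ccr1, a chemokine receptor gene. In the replicates' own lists Ccr1 had 16 ± 1.41 and Zfp217 16.5 ± 0.707 (SD, n = 2). After Fli1 came Celf5 and Zfp217 with 20 each, and Btn1a1, the G protein gene Gna15 and the cytokine receptor genes Il21r and Il4ra with 19 each. Celf5 and Gna15 are neighbours on chromosome 10, as are Il21r and Il4ra on chromosome 7, so their windows share regions. Windows of some list members overlap too, such as those of S100a8 and S100a9 on chromosome 3 and of Fli1 and Ets1 on chromosome 9. Random lists were drawn gene by gene, so the permutation p-values do not allow for such sharing. With only the 50% of regions strongest in signal, 5 lists passed the threshold, and the stem, endothelial, housekeeping, cell cycle and cytokine lists no longer did (permutation test, adjusted p = 0.103 to 0.228). Without replicate 1 the stem and endothelial lists did not pass (adjusted p = 0.0593 for both) and the neuronal list passed on the lower side (adjusted p = 0.0490), and without replicate 2 the stem list did not pass (permutation tests, adjusted p = 0.0623). In other peak lists, windows or matching, the stem list also failed at 0.0784 to 0.113, the endothelial list at 0.0516 to 0.0633 and the cell cycle list at 0.0521 and 0.108, and the neuronal list passed on the lower side without matching at 0.0424 (adjusted p, permutation tests).

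**Figure D4:**
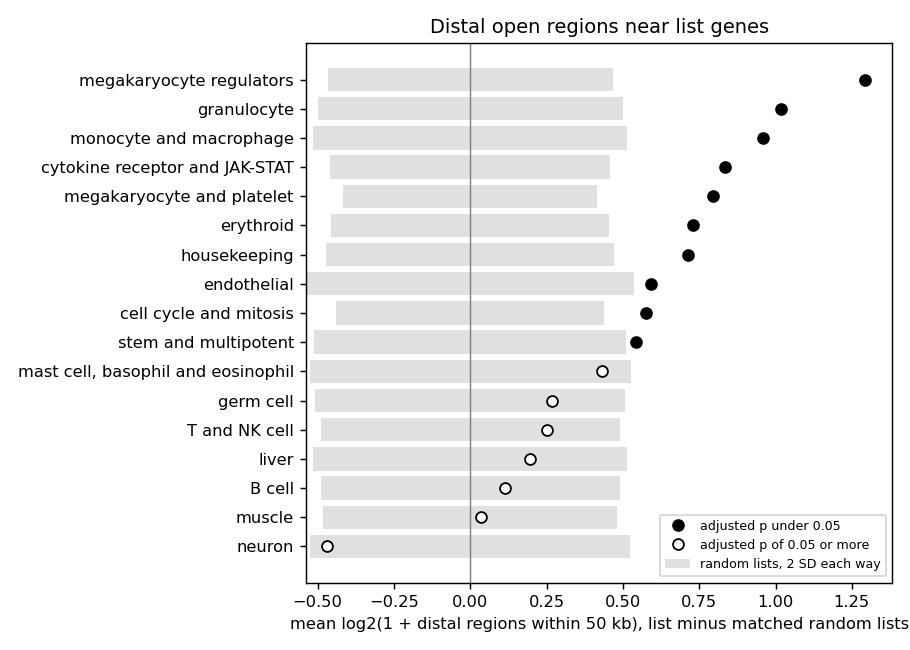
Mean log2(1 + distal regions within 50 kb) of each list minus that of random lists matched on gene density (horizontal axis), with 2 SD of the random lists each way (grey bars). Filled points passed an adjusted p of 0.05, and the megakaryocyte regulators lay highest at 1.29.

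The pooled megakaryocyte lists were compared with 7 other blood lineage lists, since the sample could hold cells of other blood lineages. A listed promoter peak does not show which cells it came from, so the comparison cannot decide whether it did. Promoter peaks were present at all 24 regulators and at 21 of 30 platelet genes (70%). Pooled, these were 45 of 54 megakaryocyte genes, 83.3%. This was higher than for mast cell, basophil and eosinophil genes (4 of 17 against 44 of 53 once the shared gene Gata2 was left out, adjusted p = 9.11e-05), T and NK cell genes (36.4%, adjusted p = 0.000611) and B cell genes (40%, adjusted p = 0.00197) by Fisher's exact test, two-sided. The difference did not pass the exact test against erythroid genes (91.7%), granulocyte and monocyte genes (75% each) with adjusted p = 0.591, nor against stem and multipotent genes (80%) with adjusted p = 0.739. These comparisons were not matched on CpG density. The median number of CpG sites per promoter was 27 for the platelet list and above the all-gene median of 61 for the regulators, against 17 for the mast cell, 23 for the B cell and 31 for the T and NK cell list. Against random lists matched on CpG density, the mast and B cell lists (adjusted p = 1 for both) and the T and NK cell list (adjusted p = 0.831) did not pass (permutation tests). With only the 50% of regions strongest in signal, 0 of the 7 comparisons passed the threshold.

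Sequence motifs of transcription factors were counted in 65547 distal summit windows of 151 bp and in 119893 flanking windows. The flanks overlapped no peak of the most inclusive list made from both libraries. Of 21 motifs 17 were more frequent at distal summits, 2 less frequent, and 2 did not pass the test. The motif of CTCF, an insulator protein, was present at 7.77% of distal summits and 0.0425% of flanks (log2 ratio 7.50). Motifs of blood factors were also more frequent: the extended MAF-NFE2 site (1.01% against 0.140%, log2 ratio 2.85), the GATA-TAL1 composite (3.17% against 0.474%, 2.74), the PU.1-type ETS site (10.8% against 1.74%, 2.63), the ETS site (5.78% against 1.15%, 2.33), the CEBP site (3.33% against 0.941%, 1.82) and the RUNX site (14.3% against 6.06%, 1.23). The short GATA site was common everywhere, at 29.8% of summits and 24.6% of flanks (0.28, exact test, adjusted p = 4.68e-129), and its ratio was 0.70 against flanks of matched GC content. The MEF2 motif was less frequent at summits (1.09% against 2.73%, -1.32, exact test, adjusted p = 1.50e-131) and the SRF motif too (-0.23, adjusted p = 0.00846), but neither passed against flanks of matched GC content, at 0.12 and 0.00. SRF also did not pass without replicate 2 (-0.14, exact test, adjusted p = 0.182) or with 100 bp windows (-0.07, adjusted p = 0.362). Against dinucleotide shuffles MEF2 was more frequent (1.30, exact test, adjusted p = 2.62e-42) and SRF less frequent (-0.27, adjusted p = 0.00448). The IRF motif was more frequent by a small ratio (0.11, exact test, adjusted p = 0.0275) that did not pass without replicate 1 (0.01, adjusted p = 0.895), without replicate 2 (0.09, adjusted p = 0.143), with 50 bp windows (0.02, adjusted p = 0.749) or in the stronger 50% (0.00, adjusted p = 1). It passed with 100 bp windows (0.14) and in replicated peaks (0.13). Its ratio was 0.73 against GC-matched flanks (exact test, adjusted p = 3.71e-33) and 1.79 against dinucleotide shuffles (adjusted p = 1.48e-136). The EBF1 motif did not pass the test at either class of summits, but was less frequent against GC-matched flanks at both (-0.67 at distal and -1.75 at promoter summits, exact test, adjusted p = 4.46e-06 and 5.12e-06). The NRF1 motif, more frequent at distal summits (2.05), did not pass against those flanks (0.83, exact test, adjusted p = 0.179). The HNF1 motif was in 0 windows. Fisher's exact test, two-sided, was adjusted over 42 tests, and several p-values were too small to be represented. Windows are not independent replicates, so p describes this peak list.

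Of the 21 motifs 12 were more frequent at 15389 promoter summits than at 24604 flanks, 5 less frequent, and 4 did not pass the test. All 12 were also among the 17 more frequent at distal summits. Of these, AP-1 (0.20, exact test, adjusted p = 0.0423) did not pass without replicate 1 (0.01, adjusted p = 1), without replicate 2 (0.06, adjusted p = 0.623), with 100 bp windows (0.05, adjusted p = 0.558) or in the stronger 50% (-0.13, adjusted p = 0.369). It passed with 50 bp windows (0.24), in replicated peaks (0.34), against GC-matched flanks (1.00, exact test, adjusted p = 2.99e-11) and against dinucleotide shuffles (0.69, adjusted p = 1.76e-09). CEBP (0.36, exact test, adjusted p = 0.0187) did not pass with 100 bp windows (0.24, adjusted p = 0.0774) or in the stronger 50% (0.21, adjusted p = 0.334), but passed in the other alternatives, at 0.36 to 3.24. The highest ratios included those of general promoter factors: NRF1 (0.812% against 0.0122%, log2 ratio 5.84), YY1 (4.50), NFY (10.9% against 1.63%, 2.73), ETS (7.93% against 1.25%, 2.66) and KLF-SP (32.2% against 6.23%, 2.37), with CTCF at 1.77% against 0.0488% (5.13). Motifs of blood factors were more frequent too, with ratios of 1.73 for MAF-NFE2, 1.46 for the GATA-TAL1 composite and 1.36 for the PU.1-type ETS site. Flanks of matched GC content were found for 6250 of the 15389 promoter summits and 61451 of the 65547 distal ones, so ratios against them describe another set of summits. In those 6250, CTCF had the highest ratio (5.09), NRF1 had 3.77, YY1 3.64, CEBP 3.24, NFY 3.10, GATA-TAL1 2.67, ETS 2.41, PU.1-type ETS 2.22 and, further down, KLF-SP 0.62. The GATA motif was less frequent at promoter summits (11.5% against 22.7%, -0.98, exact test, adjusted p = 2.60e-181), and the RUNX motif did not pass (-0.11, adjusted p = 0.0878). In the 6250 GC-matched promoter summits both were more frequent than in flanks, GATA at 20.3% against 13.3% (0.61, exact test, adjusted p = 1.39e-25) and RUNX at 8.06% against 4.93% (0.71, adjusted p = 2.05e-12). Against dinucleotide shuffles of all 15389 the ratios were 0.33 for GATA (exact test, adjusted p = 3.56e-11) and 0.85 for RUNX (adjusted p = 4.01e-24). Of the other less frequent motifs, IRF was more frequent in the matched summits (1.07, exact test, adjusted p = 2.27e-07), and E-box CAGATG, SRF and MEF2 did not pass. The E-box CAGCTG motif, more frequent in the main comparison (0.43), did not pass either (-0.09). GC content was 62.8% at promoter summits against 45.7% in their flanks, and 50.4% against 44.7% for distal summits.

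**Figure D5:**
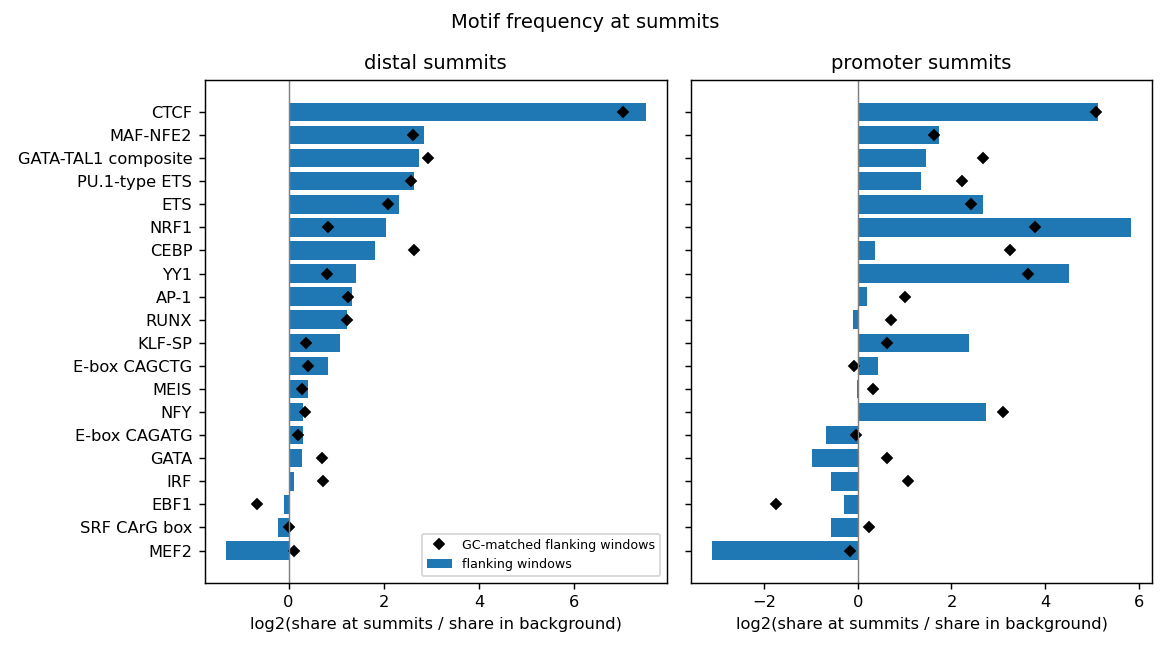
Log2 ratio of the share of windows with each motif at summits to that in flanking windows (bars) and, over the 61451 distal and 6250 promoter summits that could be matched, to that in GC-matched flanking windows (diamonds), for distal (left) and promoter (right) summits. CTCF had the highest distal ratio, 7.50, and NRF1 the highest promoter ratio, 5.84.

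The strongest region outside promoters lay 12.985 kb from the nearest gene 5′ end, that of Abcb11, the bile salt export pump gene (chromosome 2, 69355473 to 69355730, intergenic, mean signal 40.04 ± 2.14, SD, n = 2). Next came a region in an intron of Gnb1l, nearest to the 5′ end of Rtl10 (chromosome 16, 18533127 to 18533396, 35.7 ± 1.45). The others were intergenic, nearest to Nxph1 (chromosome 6, 9889880 to 9890223, 30.7 ± 0.421), Gm15319 (chromosome 8, 20424238 to 20424960, 28.8 ± 1.82) and G6pd2 (chromosome 5, 60042655 to 60043142, 29.6 ± 0.139). The nearest gene 5′ end was 942 kb away for Nxph1 and 1766 kb away for G6pd2. Other annotated start sites of a gene were not used for these distances. The regions near Abcb11, Nxph1 and G6pd2 held stretches of 129, 310 and 383 bp that matched the mitochondrial genome at 100%, 95.5% and 97.9% identity. The regions near Gm15319 and Nxph1 had 5 and 2 copies in the reference, counting the region itself. The mitochondrial genome was among the sequences searched for copies. The second copy of the Nxph1 region may therefore be its mitochondrial match of 310 bp.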

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

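The test on the 5 strongest regions was chosen only after the result was seen. The ranked list of matched summits held pairs outside the regions analysed. It had 264 pairs on 21 unplaced or unlocalized sequences, and 97 of these had an IDR of 0.05 or less. They entered the correlations over summit pairs but no location, gene or motif result. On assembled chromosomes, 143 pairs with an IDR of 0.05 or less were left out of the conservative list, which held 118746 of the 118986 pairs at that limit. The largest group of left-out pairs, 19, lay on chromosome 17 between 39843019 and 39848811, with signals of at most 2.03. Another 15 lay on chromosome 9 between 3000979 and 3036179, with signals of at most 7.15. The highest signal among the 143 was 39.7. Why these pairs were left out was not tested.

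Among the 100 strongest regions outside promoters, 4% matched the mitochondrial genome (exact 95% upper bound 9.93) and 9% had a second copy (upper bound 16.4), against 0% and 2% of 100 random other regions. Both bounds argue against either source for most of the 100 regions. They cannot exclude it for a smaller part. The mitochondrial genome was also searched for second copies, so the shares can overlap. The regions came from the conservative list, so the 143 pairs on chromosomes that this list left out were not covered. The NFY motif was more frequent at the 100 strongest summits than at other distal summits (9% against 2.17%, Fisher's exact test, adjusted p = 0.00742), which leaves sites of such a factor open for part of the set. Among the 5 strongest, 3 matched the mitochondrial genome against 1 of the next 95 (Fisher's exact test, p = 0.000244), but the matches had been seen before this test was chosen, so mitochondrial reads placed on nuclear copies stay an open explanation for these regions. Beyond the motif test no biological explanation was tested, since the design has 1 group.

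The signal ratio between the replicates was weighed in the same way. Its Spearman correlation with GC content was 0.0442 across shared regions, and the median log2 ratio of promoter regions was above that of other regions by 0.0107. The correlation argues against GC bias of one library as a source of most of the spread. The small difference of medians argues against a shift of promoter regions relative to the rest, but does not measure the spread. Both values cover only regions listed in both replicates. Depth remains open, since it is unknown.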

How the results depend on the processing

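Gene 5′ ends were counted first for matching, and annotated start sites, as planned, replaced them after results had been seen. With either count 10 lists passed the threshold. Where values moved, the cause was not tested, except that matching on GC content removes a difference in base composition by construction and also leaves out the summits without a match. Depth per library is unknown, which limits any reading of regions near the threshold.

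Sharing was 81.9% and 84.1% for replicates 1 and 2 with reciprocal overlap, 95.9% and 96.9% for the stronger 50% of regions, and 87.7% for replicate 1 with pseudoreplicated lists. Pearson's r was 0.920 on -log10 p, 0.917 with pseudoreplicated lists and 0.928 with reciprocal overlap. The promoter share was 14.8% in replicated peaks, 15.2% in pseudoreplicated peaks, 22.0% in the stronger 50%, 16.03% and 22.95% with windows of 0.5 and 2 kb, and 22.3% to 22.7% without one replicate.

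With the stronger 50% of regions, 5 promoter lists and 5 distal lists passed, 0 lineage comparisons did, and log2 odds ratios were -0.63 for megakaryocyte regulators and -0.23 for housekeeping genes, neither past the threshold. The platelet list passed with pseudoreplicated peaks (1.86, exact test, adjusted p = 0.0163) and with CpG matching (19.7 percentage points, permutation test, adjusted p = 0.0452), and mast cell genes had 0.657 points with CpG matching, not past it. In the other settings the platelet list did not pass (exact tests, adjusted p = 0.0712 to 1.00), with log2 odds ratios from -1.08 in the stronger 50% to 1.41 in replicated peaks, and -0.46 to -0.04 without one replicate. Distal regions of the platelet list (0.48 to 0.95) and of the regulators (0.59 to 1.37) passed in all alternatives run. Of the alternative values, 136 of 162 for promoter lists, 195 of 216 for distal lists and 60 of 64 for lineages were kept. For motifs, 155 of 168 distal and 140 of 168 promoter values were kept. A single list, lineage or motif was kept with the same direction and side of the threshold, where a value not past it has no direction. The totals also include, for each alternative, the count that passed (for motifs, as more frequent), kept where it stayed near the main count. Smaller shares were kept for location (2 of 32), replicate overlap (3 of 9), replicate correlation (5 of 8) and named genes (424 of 597). There a value was kept when it moved by less than a spread. This was mostly the SD of both replicates and, for correlations, an interval from leaving out each chromosome.

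With GC-matched flanks, promoter GATA (0.61), RUNX (0.71), MEIS (0.33) and IRF (1.07) passed as more frequent, and distal SRF (0.00348) and MEF2 (0.12) and promoter E-box CAGCTG (-0.0914) and SRF (0.24) changed sign without passing. With dinucleotide shuffles, distal MEF2 (1.30) and promoter GATA (0.33), RUNX (0.85), E-box CAGATG (0.23), MEIS (0.37), IRF (2.22) and MEF2 (1.5) passed as more frequent and distal NFY (-0.32) as less frequent, while promoter E-box CAGCTG (-0.0287) and SRF (0.47) did not pass. Promoter AP-1 was -0.13 in the stronger 50%, not past the threshold. Promoter RUNX passed as less frequent at -0.19 with 100 bp windows, -0.30 in the stronger 50%, and -0.22 to -0.19 without one replicate.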

Other observations

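The comparisons in this part were chosen after their values were seen, and none was tested. The X chromosome carried few open regions. It had 12.01 regions per Mb, against 26.2 to 43.8 on the 19 autosomes, and 8.89 and 8.62 in the lists of replicates 1 and 2. Chromosome 12, with a similar gene density (5.50 protein-coding genes per Mb against 5.80 on X), had 28.6 regions per Mb. The Y chromosome had 22 regions, 0.250 per Mb. The mice were male, and none of these densities was adjusted for chromosome copy number.

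Among list genes with a promoter peak, the median promoter signal was 18.1 in the germ cell list (3 genes) and 14.5 in the B cell list (8 genes), against 11.2 over all genes with a promoter peak, 7.67 in the megakaryocyte and platelet list and 7.92 in the housekeeping list.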
